A study of Arabidopsis thaliana with 6 samples.

How the data were processed

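Gene expression was measured in total RNA from 12-day-old Arabidopsis thaliana seedlings, 3 samples of the wild type and 3 of the TOC1 overexpressor. Per the labels' protocols, seedlings grew on MS3 medium, RNA was extracted with a commercial column system, and biotin-labelled cRNA made from 1 µg of RNA was hybridised to Affymetrix arrays. The deposited values are on the log2 scale. They come as 1 table of 22810 probe sets by 6 arrays. Per the submitters' processing notes, GCRMA and limma were used; their versions are not given in the sources used here. GCRMA corrects background with the probe sequence, normalizes by quantiles and summarises the probes of a set on the log2 scale. It draws dim probe sets together near the bottom of the scale, so that fold changes of transcripts low in either group are compressed. Of the values, 36.5% lay under 4, and 91 of the calls had a group mean under 4. No raw scanner files were used here.

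Groups and replicate numbers were taken from the sample titles, and every column was used. The series text calls the samples biological replicates. Affymetrix control probe sets (64) were left out of the tests, and all 22746 others were kept whatever their level. The comparison, TOC1-ox minus WT, was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, two-sided, group as the only term). P-values were adjusted by Benjamini-Hochberg over all tested probe sets, and an adjusted p under 0.05 was a call. The prior had 1.02 degrees of freedom, which gave 5.02 in all. The errors of differences are limma's standard errors, and the errors of group values are SDs over 3 arrays. There is no sequencing depth in array data, and the number of arrays limits the precision.

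Probe sets were named from the platform annotation used here, with symbols and loci updated by gene identifier from a table of the TAIR10.1 assembly. A single gene was listed for 13513 of the tested probe sets (59.4%, 13356 genes), several for 503 and none for 8730. The annotation lists no probe set for many well-known genes, TOC1 and most of the clock genes among them. The level of TOC1 itself, planned as the first value and as a check on the labels, was therefore not analysed here under its name, and a called probe set without a listed gene may be that of TOC1. Probe sets with several genes were not named. No genome build is stated for the array, so no coordinates are given.

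Named genes followed a rule set before the data were examined: TOC1, every measured clock gene of the fixed lists, the 12 largest rises and 12 largest falls among calls with a single gene, a mean log2 value of at least 4 and no overlap between groups, and from each other fixed list up to 4 called members with the largest change or, where it had none, the 2 with the largest difference as values. Any other gene named in the text was chosen after its values were seen. Of 25 lists fixed at the same time, with 403 members, 50 members (12.4%) could be measured under a name. Lists with at least 3 measured members were tested with limma camera at a preset correlation of 0.01, with an estimated correlation and with fry, each adjusted over the lists tested. A gene was represented by its probe set with the highest mean over all arrays. Because so few members could be measured, 20 further lists were drawn up from the annotated symbols before any fold change was seen, and 30 families of at least 8 genes were formed from the letters that open a symbol. These were tested in the same way and are reported among the other observations.

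The procedure was tested on simulated data with 22746 probe sets, drawn independently for each probe set and array with the spread of this comparison. It recovered 28, 39, 46 and 47 of 50 probe sets changed by log2 1, 2, 3 and 4. Of its 164 calls, 4 (2.44%) were false. No simulated array stood apart as TOC1-ox replicate 3 did in the data, so these rates do not cover such an array. Camera found all 20 simulated lists of 4 genes at each of 2 sizes of shift and 0 of 200 unshifted lists; these lists were simulated without correlation between their genes, so the test does not cover correlated lists. Alternatives tried were quantile normalization, centring of arrays, 2 filters on dim probe sets, a variance trend, a robust prior, array weights, the replicate number as a block, each array left out, a 2-fold minimum, 1 probe set per gene and the mean of a gene's probe sets. Added after the data were seen were a batch term for the arrays numbered 3, which the labelling spike-ins set apart, and fits of the arrays numbered 1 and 2 only. Camera with an estimated correlation and each array left out was also added then. Ranges of an adjusted p over all settings cover the normalizations, filters, variance models, array weights, the block, the batch and the left-out arrays, with camera at its preset correlation. Figures were drawn with matplotlib 3.10.9.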

Results

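Transcript levels were measured on 6 Affymetrix arrays in seedlings of Arabidopsis thaliana, ecotype Col-0. Wild-type (WT) seedlings were compared with seedlings of a TOC1 overexpressor (TOC1-ox), with 3 arrays per group, which the series describes as biological replicates. TOC1 is an evening-expressed component of the plant circadian clock, and the comparison asks which transcripts differ when its level is raised. The seedlings were 12 days old and had grown in cycles of 12 h light and 12 h dark. All were harvested at zeitgeber time 15, which falls in the dark part of the cycle. The deposited table holds a log2 value for each of 22810 probe sets on each array, and 22746 of them were tested after 64 control probe sets were left out. Array medians lay between 6.17 and 6.27. The number of arrays limits the precision of every value given here.

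The arrays did not lie equally far apart within the groups. TOC1-ox replicates 1 and 2 correlated at r = 0.996 across probe sets, and 177 probe sets differed more than 2-fold between them. TOC1-ox replicate 3 correlated with them at 0.977 and 0.978 and differed more than 2-fold from them at 2480 and 2298 probe sets. Its correlation with WT replicate 3 was 0.981. The WT arrays correlated with each other at 0.989 to 0.994. These correlations run across probe sets, which are not independent replicates. The first principal component held 61.2% of the variance and the second 20.7%. On the first, the WT arrays lay at -51.2 to -40.6, TOC1-ox replicates 1 and 2 at 66.2 and 63.3, and TOC1-ox replicate 3 at 7.34. RNA quality, read as the mean log2 difference between the 3′ and 5′ probe sets of 6 Arabidopsis control pairs, was 1.34 ± 0.08 in WT and 1.35 ± 0.09 in TOC1-ox (SD, n = 3 each). The difference was 0.0145 (exact two-sided permutation test, p = 0.9), where the smallest p that 3 against 3 arrays allow is 0.1. TOC1-ox replicate 3 had the lowest value of the 6 arrays, 1.25. The bacterial Dap, Lys, Phe and Thr transcripts, which are spiked in to control the labelling, set both arrays numbered 3 apart. Their median over 24 probe sets was 7.59 in WT replicate 3 and 7.01 in TOC1-ox replicate 3, against 2.81 to 4.84 on the other arrays, and all 24 were highest on those 2 arrays.

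Anthocyanin enzymes and an antenna protein of photosystem II were among the largest rises in TOC1-ox seedlings. The anthocyanin glycosyltransferases UGT75C1 and UGT79B1 rose by log2 4.43 ± 0.58 and 4.34 ± 0.49 (standard error, n = 3 each; limma, adjusted p = 0.0428 and 0.0329). The anthocyanin malonyltransferase gene 5MAT rose from a log2 value of 3.54 ± 0.53 in WT to 7.53 ± 0.51 in TOC1-ox (SD; adjusted p = 0.0243). LHCB4.3, which encodes a minor antenna protein, rose 17.0-fold, from 6.64 ± 0.07 to 10.73 ± 0.34 (adjusted p = 0.00639). AT4G33720, a member of the CAP family that includes the pathogenesis-related PR-1 proteins, rose to 7.61 ± 1.23 from 2.22 ± 0.28 in WT, near the bottom of the scale, where a fold is not well defined (adjusted p = 0.0383).

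The other named rises were of several kinds. AT5G14650, which encodes a pectin lyase-like protein, rose by log2 4.41. AT4G33560, of a wound-responsive protein family, rose by log2 4.07, and AT2G19970, another CAP family gene, by 3.71. AT5G09570, which encodes a twin-cysteine protein of the Cox19 type, rose by 3.77 and AT1G43910, which encodes a P-loop nucleotide-binding protein, by 3.71. AT1G65500 and AT3G19550 rose by 3.93 and 3.70. In these 7 genes all 3 TOC1-ox values lay above all 3 WT values, as the naming rule required. Limma's adjusted p ran from 0.0111 for AT1G43910 to 0.0417 for AT3G19550. The WT values of AT5G14650 lay near the bottom of the scale, at 2.00 to 2.19, and the WT mean of AT3G19550 was 2.77, so the sizes of these 2 rises rest on levels that are not well defined.

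THI2.2, AT3G17520, AT2G28490, DELTA-VPE, AT2G25890 and PDF2.1 were among the largest falls. The thionin gene THI2.2 fell from a log2 value of 7.59 ± 0.12 in WT (SD, n = 3) to 2.59, 2.55 and 1.77 in TOC1-ox replicates 1 to 3 (limma, adjusted p = 0.0066). The defensin gene PDF2.1 fell by 3.88 ± 0.34 (standard error), from a mean of 10.33 to 6.45 (adjusted p = 0.0216). AT3G17520, of the late embryogenesis abundant family, fell by 4.78, AT2G28490, which encodes a cupin related to seed storage proteins, by 4.58, and the oleosin-family gene AT2G25890 by 3.93 (adjusted p = 0.0409, 0.0337 and 0.0127). DELTA-VPE, a vacuolar processing enzyme known from the seed coat, fell by 4.04 (adjusted p = 0.0421). Seed material that differed between the samples may contribute to falls of such genes. This was not tested for AT3G17520, AT2G28490 and AT2G25890. The TOC1-ox values of THI2.2 and the means of AT3G17520 (2.76), AT2G28490 (2.45), AT2G25890 (2.29) and DELTA-VPE (2.64) lay near the bottom of the scale, so the sizes of these falls are not well defined.

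The remaining named falls were of other kinds. AT1G62510, which encodes a lipid-transfer and 2S albumin-like protein, fell by 3.81, the RING-finger gene AT5G47610 by 3.76 and the type 2C protein phosphatase gene AT3G16800 by 3.70. AT1G54870, of the short-chain dehydrogenase family, fell by 3.64 and the SAUR gene AT3G53250 by 3.50. COR27, a cold-regulated gene whose protein also acts on the clock, fell by 2.92. Limma's adjusted p for these 6 genes ran from 0.00594 for AT3G16800 to 0.0385 for AT1G54870. All 3 TOC1-ox values of each lay below all 3 WT values, as the naming rule required. The TOC1-ox means of AT3G16800, AT5G47610 and AT1G54870 were 2.54, 2.65 and 2.43, near the bottom of the scale, where fold changes are compressed.

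**Figure D1:**
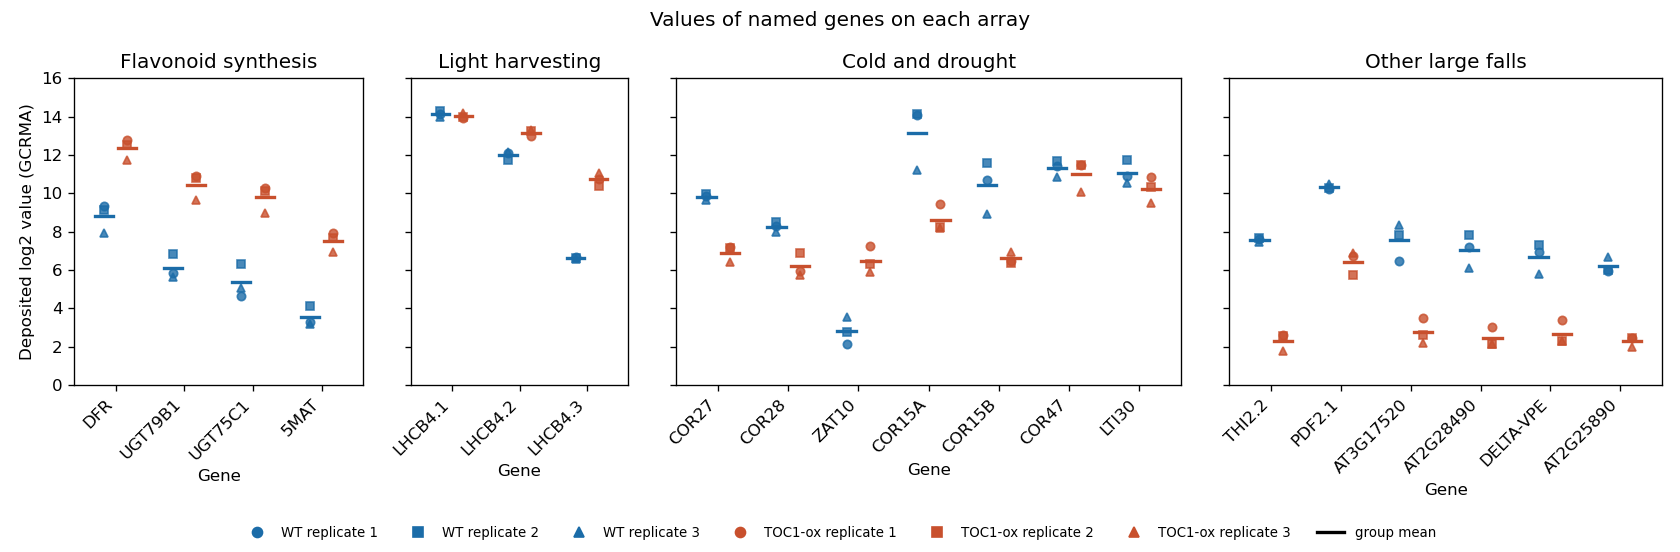
Deposited log2 values (vertical axis) of 20 genes (horizontal axis) on each of the 6 arrays, blue for WT and orange for TOC1-ox, with the marker shape giving the replicate number and lines the group means. DFR, UGT79B1, UGT75C1 and 5MAT lie higher on every TOC1-ox array than on any WT array, COR27 and THI2.2 lie lower, and LHCB4.1 differs by -0.12.

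In all, 405 of 22746 probe sets (1.78%) passed an adjusted p of 0.05 (limma, Benjamini-Hochberg). Of these, 245 were higher in TOC1-ox and 160 lower, with median folds of 3.26 and 2.46. At least 2-fold changes were seen in 189 of the higher and 101 of the lower calls. The groups did not overlap at any of the 405, and over all probe sets 4566 had no overlap, against 2275 (10%) by chance. A single gene was listed for 183 of the calls, 106 higher and 77 lower, 4 had several genes and 218 had none listed. The largest rise of all 22746 was at a probe set without a listed gene (log2 9.71, from a mean of 3.14 to 12.85, limma adjusted p = 0.0183). Its WT mean lay under 4, so the size of this rise is not well defined. The rise with the smallest p among those without a gene (7.95e-07; limma, adjusted p = 0.00594) had means of 8.56 in WT and 14.12 in TOC1-ox. The 2 largest falls called without a listed gene went from 11.13 to 6.13 and from 8.14 to 3.25 (limma, adjusted p = 0.0305 and 0.0461). The mean of 3.25 also lay under 4, which leaves the size of that fall not well defined. Whether any of these probe sets measures TOC1 itself, and so the overexpressed transcript, cannot be read from the annotation used.

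These counts depended on single arrays and on the settings. Without TOC1-ox replicate 3, limma called 1603 probe sets higher and 1352 lower, and all 405 calls were among them; without WT replicate 2, it called 5 and 3. Without WT replicates 1 and 3 and TOC1-ox replicates 1 and 2 in turn, the calls numbered 65, 188, 38 and 20. All 405 calls kept their sign in each of these fits. That was fixed in advance, since the groups did not overlap at any of them. Higher calls were 60.5% of all with 6 arrays of equal weight but 46.5% with array weights, which gave 2877 higher and 3305 lower, and 46.3% without WT replicate 3. A mean log2 value of at least 4 gave 519 higher and 333 lower, and at least 6 gave 378 and 263. Centring the arrays gave 253 lower and a robust prior 97. Of the 27 named genes called with all arrays, none passed without WT replicate 2. LHCB4.3, THI2.2, AT3G16800 and AT3G53250 passed in the other 5 fits, and 14 passed only without TOC1-ox replicate 3, among them the 4 flavonoid genes, COR27, ZAT10, LHCB4.2, DELTA-VPE, AT3G17520 and AT4G33720. Quantile normalization of the deposited values left 248 calls, 153 higher and 95 lower. It ended 9 of the 27 calls, those of UGT75C1, DFR, LHCB4.2, ZAT10, AT3G17520, DELTA-VPE, AT1G54870, AT4G33720 and AT3G19550, with adjusted p of 0.0503 to 0.0676. With the arrays numbered 3 as a batch term, limma called 314 higher and 254 lower, and AT3G17520, AT3G19550 and ZAT10 did not pass (adjusted p = 0.0573, 0.059 and 0.0702). Among the arrays numbered 1 and 2 only, it called 1170 and 1031, and AT3G17520, DELTA-VPE, UGT75C1, AT1G65500 and LHCB4.2 did not pass (0.0502 to 0.0808); the arrays numbered 3, 1 per group, allow no test of their own. With the replicate number as a block, limma called 0 probe sets, and 0 of the 27 genes passed. The block leaves fewer residual degrees of freedom. At an unadjusted p under 0.05 by limma there were 4317 probe sets with the block and 3725 without it. The labels do not state that same-numbered arrays are paired. Over all settings tried, limma's adjusted p of the 27 genes ran from 0.000578 to 0.173.

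**Figure D2:**
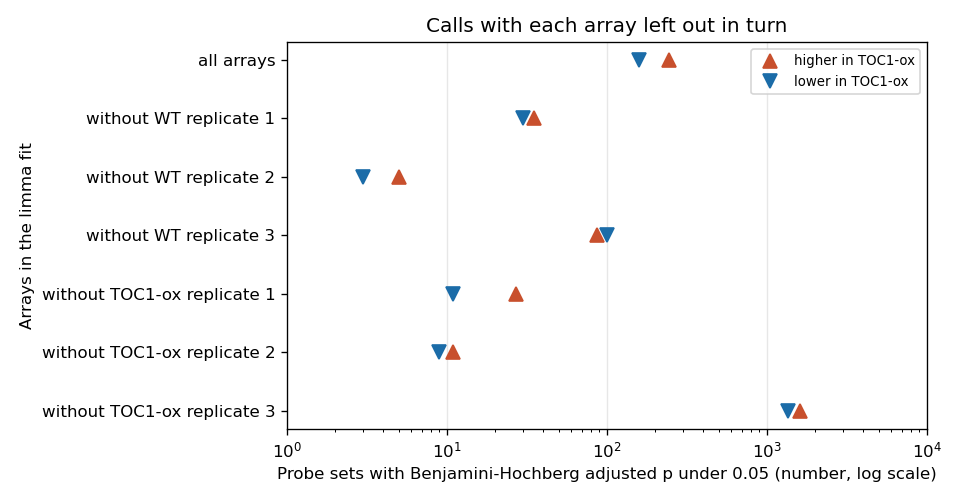
Number of probe sets with a limma Benjamini-Hochberg adjusted p under 0.05 (horizontal axis, log scale) with all 6 arrays and with each array left out (vertical axis), upward triangles for higher and downward triangles for lower in TOC1-ox. With all arrays 245 were higher and 160 lower, against 1603 and 1352 without TOC1-ox replicate 3.

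The flavonoid list had the smallest camera p of the gene groups fixed beforehand. All 4 of its measured members rose, both over all probe sets and adjusted over the list alone: UGT75C1, UGT79B1, 5MAT and DFR, the gene of dihydroflavonol reductase (log2 3.55 ± 0.48, 11.7-fold, limma adjusted p = 0.0469). The list was shifted up (limma camera, preset correlation, adjusted p = 8.15e-08), with a median log2 difference of 4.17. With an estimated correlation between genes the call was lost (adjusted p = 0.196). TOC1-ox replicate 3 lay below replicates 1 and 2 in all 4 genes, and its median over the list was 3.48 above WT against 4.59 and 4.42.

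Of the light-harvesting proteins, 2 of 3 measured members rose, also when adjusted over the list alone. LHCB4.2 rose 2.26-fold, from 11.99 ± 0.23 to 13.17 ± 0.17 (SD, n = 3 each; limma, adjusted p = 0.0421), beside LHCB4.3, while their paralog LHCB4.1 stood at 14.14 in WT and 14.02 in TOC1-ox (adjusted p = 0.723). Camera placed the list up (adjusted p = 0.00288), and with an estimated correlation the adjusted p was 0.196. All 3 members were higher in TOC1-ox replicate 3 than in replicates 1 and 2. Without replicate 3 the list's adjusted p was 0.0506, with array weights 0.129, and among the arrays numbered 1 and 2 only 0.187, in a range of 0.000929 to 0.187 over all settings. No member of the photosystem subunits (4 measured) or of chlorophyll synthesis (4 measured) passed the test, over all probe sets or adjusted over the list alone. PSBW and PSAE1 differed by -0.12 and 0.03, and camera gave the photosystem list an adjusted p of 0.976, with a positive direction although its median was -0.01 and its mean -0.03. PORB and CHLM, 2 enzymes of chlorophyll synthesis, differed by -1.21 and -0.89 (adjusted p = 0.164 and 0.337; camera for the list, 0.31). In TOC1-ox replicates 1 and 2 their values lay between 9.79 and 10.21. In replicate 3, CHLM had 11.39, within the WT values of 11.35 to 11.60, and PORB had 10.98, below the lowest WT value of 11.34. Without replicate 3, PORB and CHLM passed (limma, adjusted p = 0.0153 and 0.00578), as they did with array weights (0.0123 and 0.0118) and CHLM among the arrays numbered 1 and 2 only (0.0241). These fits called 2955, 6182 and 2201 of 22746 probe sets, against 405 in the main fit. Over all settings the adjusted p ran from 0.0123 to 0.398 for PORB and from 0.00578 to 0.678 for CHLM. Camera placed the chlorophyll synthesis list down without replicate 3 (adjusted p = 0.0158, in a range of 0.0158 to 0.735 over all settings). With an estimated correlation the list's adjusted p was 0.305 without replicate 3 and 0.629 with all arrays.

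Members of the cold-response list changed in both directions. COR27 fell, and ZAT10, a zinc-finger repressor induced by several stresses, rose from 2.82 ± 0.70, near the bottom of the scale, to 6.48 ± 0.70 (SD, n = 3 each; limma, adjusted p = 0.0485). COR28, the close relative of COR27, differed by -2.06 (adjusted p = 0.064). Adjusted over the list alone, 1 member rose and 2 fell, against 1 and 1 over all probe sets, and camera did not call the list (adjusted p = 0.31). All 3 members were lower in TOC1-ox replicate 3 than in replicates 1 and 2. None of the 4 measured drought- and ABA-responsive genes passed over all probe sets, and 2, COR15A and COR15B, were lower when adjusted over the list alone. These proteins protect chloroplast membranes during freezing. COR15A had log2 values of 13.15 ± 1.68 in WT and 8.63 ± 0.71 in TOC1-ox and COR15B 10.41 ± 1.36 and 6.62 ± 0.30 (SD, n = 3 each; limma, adjusted p = 0.1 and 0.0826). LTI30 and COR47, also on this list, differed by -0.81 and -0.33 (limma, adjusted p = 0.512 and 0.863). Camera placed this list down (adjusted p = 0.0302), and the adjusted p was 0.557 with an estimated correlation. The call also ended without TOC1-ox replicate 3 (0.309), without WT replicates 2 and 3 (0.0561 and 0.0863), after quantile normalization (0.0719), with array weights (0.129) and among the arrays numbered 1 and 2 only (0.267), in a range of 0.00742 to 0.309 over all settings. COR15A had 11.22 in WT replicate 3 against 14.11 and 14.13 in replicates 1 and 2. With all 6 arrays, COR15A and COR15B passed over all probe sets with a mean log2 value of at least 4 (limma, adjusted p = 0.0282 and 0.0216) or at least 6 (0.0259 and 0.0201) and with array weights (0.00504 and 0.00302), and COR15B with a variance trend (0.0408). Both passed among the arrays numbered 1 and 2 only (0.0403 and 0.0332), and COR15B without WT replicate 3 (0.0488). Array weights called 6182 of 22746 probe sets and the arrays numbered 1 and 2 only 2201, against 405 in the main fit. Over all settings the adjusted p ran from 0.00504 to 0.287 for COR15A and from 0.00302 to 0.267 for COR15B.

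Clock genes could be read at 2 loci of the fixed lists. RVE6, a daytime MYB-like clock factor, stood at 6.91 ± 0.13 in WT and 5.80 ± 0.96 in TOC1-ox (SD, n = 3 each), a log2 difference of -1.11 that did not pass (limma, adjusted p = 0.374). Its TOC1-ox values were 6.28, 6.43 and 4.69 in replicates 1 to 3. Without replicate 3 the difference was -0.55 and passed (limma, adjusted p = 0.0444; 0.0444 to 0.628 over all settings). GI lay at the bottom of the scale in both groups, with means of 1.95 and 1.90 (adjusted p = 0.779). TOC1 and the other clock genes of the lists are not analysed here, since the annotation used pairs no probe set with them.

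No member of the remaining fixed lists passed over all probe sets. Among 4 starch genes, APL3 and DPE1 differed by 1.86 and -0.89 (limma, adjusted p = 0.133 and 0.113); adjusted over the list alone, 2 were higher and 1 lower. Adjusted over the list alone, WRKY53 of the pathogen-response list (log2 2.54), ROF2 of the heat-shock list (2.12) and EXP7 of the root list (0.84) were higher, 1 member each. These lists had only 2, 1 and 2 measured members. For ROF2 that is therefore no adjustment at all, and none was made for the number of lists looked at. Over all probe sets the adjusted p of WRKY53, ROF2 and EXP7 was 0.11, 0.0933 and 0.129 (limma). In the glucosinolate list, BCAT4 and UGT74B1 differed by -2.56 and 0.45 (adjusted p = 0.555 and 0.464), with BCAT4 at 4.66, 5.84 and 10.57 in TOC1-ox replicates 1 to 3 against a WT mean of 9.58. The list's median and mean were negative and camera's direction positive (adjusted p = 0.976). None of the following was called by either count: SAG101 (0.69), FHL and IAA29 of the shade and auxin list (1.62 and 0.33), HYH of light signalling (0.49), PDF1.2 of the jasmonate list (0.26), AGL24 and CDF5 of photoperiodic flowering (-0.10 and -0.00267), AUR2 and AUR1 of the cell cycle (-0.57 and -0.01) and the root marker PYK10 (0.04). HYH stood at 3.13, 2.76 and 5.26 in TOC1-ox replicates 1 to 3, FHL at 8.90, 9.11 and 4.91 and IAA29 at 2.27, 3.42 and 2.27. Their WT means were 3.23, 6.02 and 2.32, so single arrays weigh heavily in these differences. FMA and MUTE of the guard cell lineage differed by 0.57 and 0.17, and the reference genes UBC21 and SAND by -0.46 and -0.14. Camera called neither list (adjusted p = 0.31 and 0.337), nor the starch list (0.428). Without TOC1-ox replicate 3, APL3, WRKY53, ROF2, EXP7, SAG101, FHL and BCAT4 passed, with limma's adjusted p from 0.00386 for SAG101 to 0.0386 for EXP7, and without WT replicate 3 DPE1 did (0.0452). With all 6 arrays, APL3, WRKY53 and ROF2 passed with a mean log2 value of at least 4 (0.0475, 0.0335 and 0.029), and APL3 and ROF2 with at least 6 (0.0443 and 0.0268). Array weights gave calls for all 8 genes and for AUR2, PYK10 and UBC21, from 0.00283 for DPE1 to 0.049 for PYK10. Of 22746 probe sets, 6182 were called with array weights and 2955 without TOC1-ox replicate 3, against 405 in the main fit. A pass in those fits therefore says less about a single gene. Among the arrays numbered 1 and 2 only, APL3, DPE1, WRKY53, SAG101 and FHL passed, from 0.0147 for FHL to 0.0411 for APL3. Over all settings the adjusted p of these genes ran from 0.00283 for DPE1 to 1 for PYK10. No member of the ABA pathway, sugar starvation, nitrate, floral organ or seed storage lists was among the measured genes with a name.

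In total 3 of the 10 fixed lists with at least 3 measured members were shifted by camera with the preset correlation. Flavonoid and light harvesting were placed up and drought response down. With the estimated correlation 0 lists were called, where the lowest adjusted p was 0.196. Few members were measured: 4 of 18 for flavonoid, 3 of 21 for light harvesting and 4 of 21 for drought response. The light-harvesting members were all LHCB4 paralogs, so these shifts do not cover whole pathways. The directional test fry, which asks whether the genes of a list move 1 way on balance and makes no comparison with other genes, passed for 4 lists: light harvesting (adjusted p = 0.00224), flavonoid (0.00545), cold response (0.0377) and starch (0.0377). For the drought list fry gave 0.0673.

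**Figure D3:**
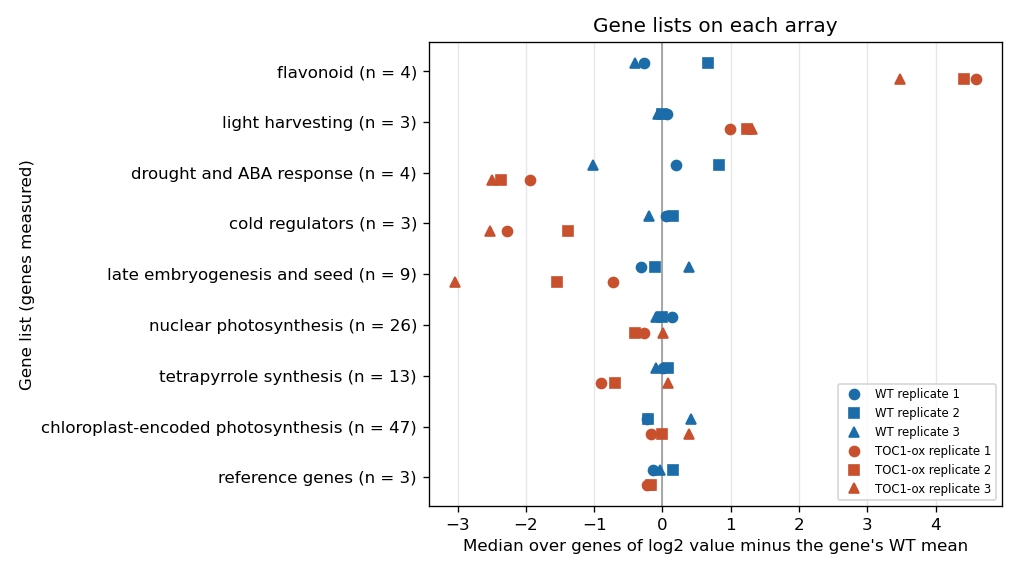
Median over the genes of 9 lists of the log2 value minus the gene's WT mean (horizontal axis), per array, blue for WT and orange for TOC1-ox, with the marker shape giving the replicate number; each list's name and number of measured genes are on the vertical axis. The flavonoid median lies 3.48 to 4.59 above WT on the TOC1-ox arrays, and for tetrapyrrole synthesis replicates 1 and 2 lie at -0.90 and -0.69 and replicate 3 at 0.09.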

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

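Chosen only after the data were seen were the runs on the further gene lists and symbol families, the batch term for the arrays numbered 3, the fits of the arrays numbered 1 and 2 only and the estimated correlations with 1 array left out. The planned run of the alternatives on TOC1 itself was not run, because no probe set is paired with it here. With all arrays and no filter, 245 probe sets higher in TOC1-ox and 160 probe sets lower in TOC1-ox were called. The counts were 153 and 95 after quantile normalization, 519 and 333 with a mean log2 value of at least 4, 378 and 263 with at least 6, and 2877 and 3305 with array weights, where 46.5% of calls were higher against 60.5%. The batch term gave 254 lower, and the arrays numbered 1 and 2 only gave 1170 and 1031. Centring arrays on their median gave 253 lower, the robust prior 97 lower, and a 2-fold minimum 101 lower. A single probe set per named gene gave 62 and 44, against 106 and 77 single-gene calls when all probe sets were fitted. Why the counts differed between settings was not tested. With 1 array left out, the counts ranged from 5 to 1603 higher and from 3 to 1352 lower. Of the 405 calls, those tested kept their sign in every setting of normalization, filter, variance model, block, batch and left-out array. Only the normalizations could have changed a sign. Without overlap between the groups, leaving out or weighting arrays cannot. The filters, variance models, block and batch term leave the difference as it was. The fixed lists past camera numbered 3, against 1 with array weights, 1 among the arrays numbered 1 and 2 only, 0 with an estimated correlation, 2 after quantile normalization, 4 with fry and 2 to 3 with 1 array left out.

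Replicate numbers were not taken to pair the arrays, since not every pair of same-numbered arrays had a correlation above 0.1: deviations of same-numbered arrays from their group means correlated at 0.299, -0.0119 and 0.0816. These correlations are not separate checks, since the deviations of TOC1-ox replicates 1 and 2 correlated at -0.869 and -0.841 with those of replicate 3. They therefore cannot settle whether the arrays were paired. With the replicate block limma called 0 probe sets higher and 0 lower, and 0 of the 27 named calls passed. The block leaves fewer residual degrees of freedom, and 4317 probe sets had an unadjusted p under 0.05 by limma, against 3725 without it. Camera's call of the further list of seed genes ended with the block (adjusted p = 0.0782, in a range of 0.00379 to 0.474 over all settings). TOC1-ox replicates 2 and 3 correlated best with another number than their own. Some controls moved with the number all the same: the labelling spike-ins had medians of 7.59 and 7.01 on the arrays numbered 3 against 2.81 to 4.84 on the others, and chloroplast-encoded photosynthesis genes were higher on both, so shared handling of same-numbered arrays stays open.

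Of 531 values of the 56 named genes under the other settings, 447 kept their side of the threshold, 51 lost the call, 33 gained it and 0 changed sign with a call. Of 336 with 1 array left out, these numbers were 216, 108, 12 and 0. Signal near the bottom of the scale limits what can be said of dim genes such as GI.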

Other observations

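Chosen only after the result was seen were the estimated correlations with 1 array left out, the tests of a shared batch in its 3 forms, RNA degradation, admixed WT RNA and seed material, and the splits of the arrays for the 2 counts of probe sets; the further gene lists were drawn up before fold changes were seen. Among 30 families formed by symbol, the UGT glycosyltransferases stood out: of 47 genes, which do not include UGT75C1 and UGT79B1, 5 rose and 1 fell. UGT73C1 rose by log2 3.55 from a WT mean of 2.93, near the bottom of the scale (limma, adjusted p = 0.0104), UGT78D2, a flavonoid glucosyltransferase, by 1.76 (0.0432), UGT84A3 by 1.70 (0.0328), UGT74D1 by 1.35 (0.0243) and UGT88A1 by 0.81 (0.0339), while UGT71C4 fell by 0.73 (0.0421). Camera placed the family up (adjusted p = 3.75e-06; adjusted p = 0.114 with an estimated correlation). TBL genes, which include cell wall acetyltransferases, had 2 rises of 22, TBL37 and TBL41 (log2 0.81 and 1.70), and camera gave the family an adjusted p of 0.00336 (adjusted p = 0.913 with an estimated correlation; 0.27 with a mean log2 value of at least 6, in a range of 0.000314 to 0.27). Fry passed for 2 of the 30 families, UGT and the genes with symbols opening with PUB (adjusted p = 0.00718 for each). It gave TBL an adjusted p of 0.423. The sugar transporter SWEET1 rose by 1.62 and SWEET4 fell by 1.89, with the 17-gene sugar transport list not called by camera (adjusted p = 0.547).

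Of the 20 further lists, camera called 2 and fry 0. Root-hair and root glucosidase genes were placed up (adjusted p = 0.00443; adjusted p = 0.855 with an estimated correlation), with 0 of 7 members called by limma, 2 higher when adjusted over the list alone, and all 7 lower in TOC1-ox replicate 3 than in replicates 1 and 2. XTH26 stood at 5.55 and 5.69 in TOC1-ox replicates 1 and 2 and at 2.35 in replicate 3, against a WT mean of 2.19. Late embryogenesis and seed genes were placed down (adjusted p = 0.0184; adjusted p = 0.855 with an estimated correlation), with 1 of 9 called, DELTA-VPE, and 4 lower when adjusted over the list alone. The list's median against WT was -0.72, -1.55 and -3.04 in TOC1-ox replicates 1 to 3, and its median difference was -2.46 with all arrays, -1.14 without TOC1-ox replicate 3 and -1.52 without WT replicate 3. The call ended without either of these arrays (adjusted p = 0.131 and 0.276), among the arrays numbered 1 and 2 only (0.474), with array weights (0.276) and with a mean log2 value of at least 6 (0.0517), in a range of 0.00379 to 0.474 over all settings. In the nuclear photosynthesis list, LHCB4.2 and LHCB4.3 rose and PGRL1B fell by 0.45 (limma, adjusted p = 0.0383), with 26 measured and camera at an adjusted p of 0.288. Without TOC1-ox replicate 3, camera placed this list and the 13 tetrapyrrole genes down (adjusted p = 0.00094 and 3.56e-05; with an estimated correlation, adjusted p = 0.7 and 0.467). The same held among the arrays numbered 1 and 2 only (0.0231 and 0.00312) and for the tetrapyrrole genes with array weights (0.0125), in ranges over all settings of 0.00094 to 0.735 and 3.56e-05 to 0.559. With all arrays and an estimated correlation the adjusted p was 0.862 and 0.855. Chloroplast-encoded genes were higher on both arrays numbered 3: against WT, the median over 47 photosynthesis genes was 0.42 in WT replicate 3 and 0.39 in TOC1-ox replicate 3, with -0.225 to -0.00817 on the other arrays, and over 22 genes of chloroplast gene expression it was 0.31 and 0.28, with -0.21 to -0.04. The photosynthesis genes had a median difference of 0.06 between the groups (camera, adjusted p = 0.167). Camera placed them up without WT replicate 3 (median 0.25, adjusted p = 1.04e-05) and without TOC1-ox replicate 1 (median 0.16, adjusted p = 0.00877). It also did so with array weights (median 0.19, adjusted p = 0.00216) and among the arrays numbered 1 and 2 only (median 0.15, adjusted p = 0.0107). The adjusted p ranged from 1.04e-05 to 0.944 over all settings. With an estimated correlation the adjusted p was 0.691 without WT replicate 3, 0.833 without TOC1-ox replicate 1 and 0.855 with all arrays. No other further list was called with all arrays; without WT replicate 1, the list of protein folding in the endoplasmic reticulum was placed down (adjusted p = 0.0461, in a range of 0.0461 to 0.963; adjusted p = 0.997 with an estimated correlation). Median, mean and test differed in sign for 8 of the 20 lists and 14 of the 30 families.

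TOC1-ox replicate 3 stood apart from the other TOC1-ox arrays: all 13 tetrapyrrole genes and 22 of 26 nuclear photosynthesis genes were higher there than in both of the others. Some features moved alike on both arrays numbered 3: the labelling spike-ins had medians of 7.01 in TOC1-ox replicate 3 and 7.59 in WT replicate 3 against at most 4.84 on the others, and 69 chloroplast-encoded genes lay a median of 0.435 and 0.526 above replicates 1 and 2 of their groups (95% bootstrap interval in WT 0.40 to 0.73). Against the WT mean, the median over 16 mitochondrial genes was 0.166 in TOC1-ox replicate 3 and 0.0792 in WT replicate 3, and at most 0.00678 on the others. The 25S rRNA control was also highest on both arrays (9.44 and 9.43, against at most 9.10), but the 5S rRNA control was not. A batch that moved both arrays alike at all genes would carry WT replicate 3 along. TOC1-ox replicate 3 differed more than 2-fold from the mean of replicates 1 and 2 at 2269 probe sets, by a median of 1.37. Over these, WT replicate 3 differed in the same direction by a median of 0.00973 (95% bootstrap interval -0.01 to 0.03). The bootstrap intervals in this paragraph resample probe sets, which are not independent, and do not measure the spread between arrays. Degraded RNA would raise the 3′ to 5′ difference, which was 1.25 against a mean of 1.37 on the other 5 arrays, and WT RNA mixed in, at the 79.2% read from 94 probe sets at least 8-fold higher in replicates 1 and 2, would raise the 32 at least 8-fold lower by a median of 3.36, where 1.23 was observed (95% bootstrap interval 0.50 to 2.11). These values argue against degradation, admixed WT RNA and a batch that moves both arrays alike as the whole cause. Such a batch stays open in the chloroplast-encoded genes, and it was not tested in the mitochondrial genes. A batch that acts differently in the groups and a difference in the state of the seedlings also stay open. They cannot be told apart, since 1 TOC1-ox array carries the number 3.

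The downward shift of the seed and late embryogenesis list may come from seed material that differed between the samples. As the only source it would move the members in 1 ratio between WT arrays, and the SD over the 7 members with a WT mean of at least 4 was 1.36 between WT replicates 3 and 1, above 99.2% of 10000 random lists matched on level. For the other pairs of WT arrays the SD lay above 99.3% and 99.95%. LEA4-5, with a WT mean of 8.28, was 2.93 higher in WT replicate 3 than in replicate 1, and DELTA-VPE differed by -1.12. This argues against a single source of fixed makeup; a partial contribution of seed material, several sources, expression of the members in seedlings themselves and an effect of the genotype stay open, untested.

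Splitting the 6 arrays into 3 and 3 gives 10 splits, too few for a share under 0.05. The real split alone (1 of 10) called as many as 245 probe sets higher and 160 lower, and the highest of the others called 0. At an unadjusted p under 0.05 by limma, the others had up to 2661 probe sets and the real split 3725. For the fixed lists, 2 of the 10 splits called at least 3. The highest of the others was 3, in the split that put TOC1-ox replicate 3 with WT replicates 1 and 3. That split held both arrays numbered 3 together, but the further splits that did so called 0 lists. Apart from the real split, those that parted these 2 arrays called up to 2 lists. With the arrays numbered 3 as a batch term, 3 lists were called. Neighbouring genes were tested for moving together: among 5221 pairs of adjacent measured genes, 1 pair, AT1G65490 and AT1G65500, was called in the same direction, against a mean of 0.492 and a 95th percentile of 2 over 10000 random placements (one-sided permutation p = 0.39).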
